A study of Mus musculus with 2 samples.

How the data were processed

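The measurement was droplet single-cell RNA sequencing of subcutaneous MC38 tumours, with 1 control library and 1 UBD overexpression library prepared with a 3' v3 chemistry, per the labels' protocols. The values used are UMI counts per gene and barcode, which the authors deposited as 1 sparse matrix per library with 31053 genes. Cell Ranger, STAR and the mm10 build are named in the submitters' processing notes. The matrix headers give software version 3.1.0, per the file headers. The annotation, the aligner settings and the rule by which barcodes were called cells are not given in the sources used here. Gene IDs were matched to GENCODE vM21 on GRCm38, the assembly that mm10 also names, for 30934 of 31053 IDs, and coordinates come from that annotation.

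Barcodes were kept with at least 200 genes, at least 500 UMIs and at most 20% of UMIs from mitochondrially encoded genes. Of 14890 control barcodes 14353 passed, and of 14158 UBD barcodes 13619. Doublets were predicted per library with Scrublet as run in scanpy, at an expected rate of 0.1 and its automatic threshold, which marked 529 control cells (3.69%) and 562 UBD cells (4.13%). These were removed, leaving 13824 and 13057 cells with 164695720 and 190086511 UMIs. Both libraries were then clustered together without batch correction: counts were scaled to 10000 per cell and logged, 2000 variable genes and 30 principal components were taken, and Leiden clustering at resolution 1.0 on 15 neighbours with seed 0 gave 24 clusters. Versions were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.

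No annotation of cells was used, so clusters were named "X-like" from marker lists of 18 classes that were fixed before the data were examined, as were the gene lists, the comparisons and all but the last 4 alternatives below. The scoring rule and its thresholds were set after seeing the data. A cluster took the class with the most markers among its 10 leading genes by fold and then the highest marker score, needed a score of at least 0.25 and at least 3 detected markers, and stayed unnamed with a median doublet score of 0.15 or more. It also stayed unnamed where markers of 2 classes led it, or where its median UMI count was below its libraries' median divided by 3 without a marker of its own among its leading genes. The planned tumour or epithelial class could not be used, since its markers led a single cluster and markers of other classes led others. In its place, also after seeing the data, stands a set of 7 clusters with the sum of 4 Y-linked genes under 10 CPM and Cdkn2a over 500 CPM, called the Y-negative clusters. The host classes needed a Y-linked sum of at least 40 CPM, a limit raised from 30 after a cluster at the lower resolution was misnamed. Cluster 9, led by Acp5, Ctsk and Mmp9, matched no marker list and is called the Acp5 and Ctsk cluster. The unnamed clusters held 13.5% of control and 3.08% of UBD cells. The largest, cluster 7, had a Y-linked sum of 23.5 CPM, between the limits, with Cdkn2a at 1611 CPM, held 1705 control and 49 UBD cells and was led by Gm42418 and Lars2. With 1 library per group, a cluster mostly of 1 library may be that library and not a type.

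With 1 library per group no test was run and no p-value or standard error was computed. UMIs were summed over the cells of a class and scaled to CPM of that sum, with exact Poisson intervals. Ratios have exact conditional binomial intervals, shares have Clopper-Pearson intervals, and differences of shares have Newcombe-Wilson intervals, all at 95%. Where a count is 0, the limit given is 3 counts. Gene lists, 30 in all, were summarised in each class with at least 100 cells in both libraries by the median log2 ratio of members with at least 20 summed UMIs. Its interval is the exact order-statistic interval over members, and its percentile is among 10000 random lists of the same size matched on mean expression. Some genes stand in more than 1 list. NK-like, neutrophil-like and endothelial-like cells had too few UBD cells (95, 31 and 27) for that comparison. For shares of T-like cells with a UMI, every cell was thinned to 1000 UMIs and shallower cells were left out.

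Genes were named by a rule of size. They needed at least 50 CPM in at least 1 library, at least 50 summed UMIs, a ratio of at least 1.5 either way and an interval that excludes 1. Genes whose level in the class was under 20% of their highest level in another named class were left out as possible free RNA. Unnamed clusters did not enter that limit. Also left out were Xist, 4 Y-linked genes, mitochondrially encoded genes and genes with provisional names. The 12 largest and 12 smallest ratios were named in the Y-negative and monocyte- or macrophage-like cells, 8 and 8 in T-like cells, and 3 and 3 in the other classes. List members given as examples are among the 4 with the most UMIs in the class, and 10 genes (Ubd, Cd274, B2m, H2-K1, H2-D1, Pdcd1, Cd8a, Foxp3, Gzmb and Ifng) were fixed by name.

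The steps were tested on simulated counts drawn from the libraries' means. Genes changed 2-fold and 4-fold were recovered in 100% of cases in the Y-negative, monocyte- or macrophage-like and T-like simulations. Genes changed 1.5-fold, at the threshold itself, were recovered in 48.3%, 52.6% and 54.4%. The rule called 0 of 2499, 0 of 2350 and 4 of 2267 unchanged genes, and the intervals held the true ratio for 95.4%, 95.3% and 95.2% of genes. These counts were Poisson draws from means pooled over both libraries, without variation between cells, clusters or tumours and without the free RNA filter. They check the computation under counting error and give no error rate for differences between 2 tumours. Alternatives were a stricter cell filter (at least 500 genes and at most 10% mitochondrial UMIs), doublets kept, Leiden resolutions 0.5 and 2.0, scaling by the median of gene ratios, cells weighted equally, minimums of 5 and 100 UMIs for list members, no free RNA filter, no thinning or thinning to 500, and shares of immune cells. Chosen after seeing the data were shares without the unnamed clusters or with the largest of them counted as Y-negative, values without cluster 5 and list medians within clusters. Scaling by the median of gene ratios shifted all log2 ratios of a class by at most 0.06.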

Results

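Subcutaneous tumours grown in mice from MC38, a mouse colon carcinoma line, were dissociated and profiled by droplet single-cell RNA sequencing of transcript 3' ends. The design holds 2 libraries, 1 from control tumour tissue and 1 from tumour tissue overexpressing UBD. UBD, also called FAT10, is a ubiquitin-like modifier that targets proteins to the proteasome and is inducible by inflammatory cytokines. The study asks how UBD bears on immune evasion and on the response to PD-1 blockade, so the comparisons below address the cell makeup of the tumours and expression within each cell class. The control library held 14890 barcodes and 173973178 UMIs, with a median of 4302 UMIs and 1578 genes per barcode. The UBD library held 14158 barcodes and 204267192 UMIs, with a median of 12006.5 UMIs and 2966.5 genes. After the cell filters and removal of predicted doublets, 13824 control and 13057 UBD cells were kept, with medians of 4333 and 12186 UMIs. There are no replicates and no replicate check of any difference, so each value describes these libraries. Intervals of counts, shares and ratios of single genes are at the 95% level and cover counting error only. Intervals of gene list medians show the spread between the genes of a list, and for lists of fewer than 6 genes they are the whole range, which covers less than 95%.

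Ubd (ENSMUSG00000035186, protein-coding, GRCm38 chromosome 17, 37193892 to 37196095, plus strand) was barely seen in either library. Over all kept cells it gave 111 UMIs in the control library and 204 in the UBD library, 0.674 CPM (0.554 to 0.812) against 1.07 CPM (0.931 to 1.23). In the Y-negative clusters, the set with high Cdkn2a and almost no Y-linked transcripts, Ubd was 0.353 CPM in the control library and 1.15 CPM in the UBD library. That is 3.25-fold higher in the UBD library (2.33 to 4.61), from 45 and 183 UMIs. Left without cluster 5, the Y-negative cluster with the most mitochondrial transcripts, the log2 ratio was 2.82 in place of 1.70, and with all cells weighted equally it was 1.00. Of the Y-negative cells, 0.584% in the control library and 1.10% in the UBD library had a Ubd UMI, at median depths of 21497.5 and 16797 UMIs. The monocyte- or macrophage-like cells, a background for a tumour-cell transgene, had a Ubd UMI in 0.124% and 0.0844% of cells at median depths of 3135 and 4679 UMIs. The highest level was in the control endothelial-like cells, 38.7 CPM from 46 UMIs in 10 of 297 cells, against 5.15 CPM from 1 UMI in the UBD library. Endothelial-like cells also carried Cdkn2a, at 1169 CPM in the control and 453 CPM in the UBD library. T-like cells gave 0 Ubd UMIs in both libraries, which allows up to 1.63 CPM in the control and 1.998 CPM in the UBD library. A 3' tag can miss a transgene that lacks the mouse 3' end or comes from another species, and in that case these counts check nothing about the overexpression.

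Of the classes below, those with the largest differences in percentage points were the Y-negative clusters, the monocyte- or macrophage-like cells and a cluster led by Acp5 and Ctsk, genes of bone-resorbing osteoclasts, beside a difference of -10.4 points in the unnamed clusters. Y-negative cells were 36.0% of control cells (35.2 to 36.8) and 63.3% of UBD cells (62.5 to 64.2), 27.4 percentage points higher in the UBD library (26.2 to 28.5). Monocyte- or macrophage-like cells were 35.1% of the control and 18.2% of the UBD library, a difference of -16.9 points (-18.0 to -15.9). The Acp5 and Ctsk cluster held 0.926% of control cells (0.773 to 1.10) and 7.31% of UBD cells (6.87 to 7.77), a share 7.89 times as large. Without clusters, cells with UMIs of both genes were 4.74 times as frequent, and 73 of 160 such control cells, against 2 of 735 UBD cells, lay in unnamed clusters. T-like cells took similar shares, 3.62% and 4.03%, with a difference of 0.412 points whose interval spans 0 (-0.0468 to 0.872). NK-like cells were 3.16% and 0.728%, dendritic-like cells 3.23% and 1.89%, and neutrophil-like cells 1.58% and 0.237%. The dendritic-like difference of -1.33 points was -0.192 at Leiden resolution 2.0. Endothelial-like cells were 2.15% and 0.207%, and fibroblast-like cells 0.796% and 1.04%. The endothelial-like difference of -1.94 points was -1.13 with the stricter cell filter. The fibroblast-like difference of 0.246 points became -0.281 at Leiden resolution 0.5 and -0.159 with doublets kept. Among immune cells alone, 6632 in the control and 4332 in the UBD library, T-like cells were 7.54% (6.92 to 8.20) and 12.1% (11.2 to 13.2). On the same scale monocyte- or macrophage-like cells were 73.1% and 54.7%, NK-like cells 6.59% and 2.19%, dendritic-like cells 6.72% and 5.70%, neutrophil-like cells 3.30% and 0.716%, and the Acp5 and Ctsk cluster 1.93% and 22.0%. Clusters without a name held 13.5% of control and 3.08% of UBD cells. The largest of them, cluster 7, carried Cdkn2a at 1611 CPM, and counted as Y-negative it would make the Y-negative shares 48.3% and 63.7%, a difference of 15.4 points. Median depth differed in both directions by class, at 21497.5 control and 16797 UBD UMIs in Y-negative cells but 3135 and 4679 in monocyte- or macrophage-like cells. The gap in depth over all kept cells thus partly reflects the shares themselves, since Y-negative cells are deep. Depth can still bear on these shares, and the yield of Y-negative cells on those among all kept cells.

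**Figure D1:**
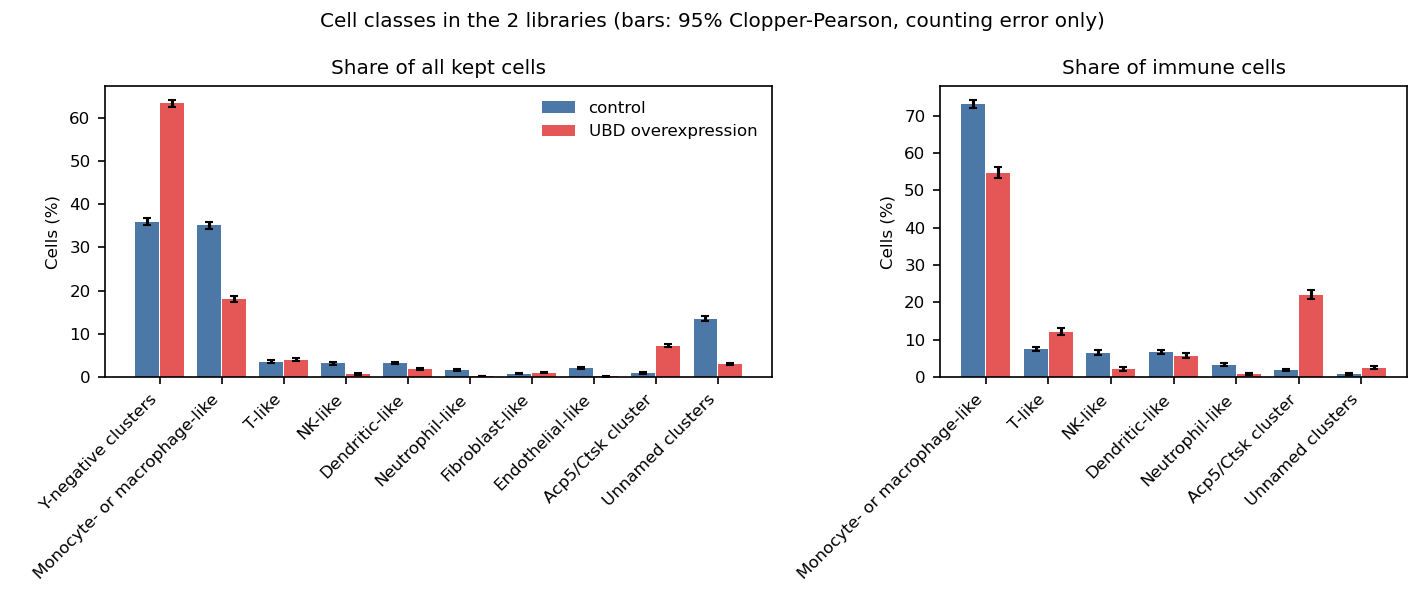
Share of each cell class among all kept cells (left) and of each immune class among immune cells (right), in percent, for the control and UBD libraries, with exact binomial intervals. The Y-negative clusters go from 36.0% in the control to 63.3% in the UBD library, and the Acp5 and Ctsk cluster from 1.93% to 22.0% of immune cells.

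Within the Y-negative clusters, interferon-stimulated genes and NF-kB targets were lower in the UBD library, and H19 and Krt18 had the largest ratios of the genes named by size. Ifit1 (ENSMUSG00000034459, chromosome 19, 34640871 to 34650009), an interferon-induced antiviral gene, was 202 CPM in the control and 20.9 CPM in the UBD library, 9.66-fold lower there (9.32 to 10.0). Cxcl10, a chemokine that attracts T cells, was 1387 and 159 CPM, 8.73-fold lower in the UBD library (8.61 to 8.84). Cluster 5, led by Cxcl10 and with Ifit1 among its leading genes, held 34.7% of control and 0.967% of UBD Y-negative cells, and without it the log2 ratios were -2.42 in place of -3.13 for Cxcl10 and -2.85 in place of -3.27 for Ifit1. Over all genes that passed the naming rule and were lower in the UBD library, the median share of the log2 ratio kept without cluster 5 was 0.821, with a 10th percentile of 0.475. Serpinb2, a plasminogen activator inhibitor, was 18.5-fold lower (16.9 to 20.2) and the cytokine Il11 10.5-fold lower (9.82 to 11.2). Also among the 12 genes with the smallest ratios were the retinoid-binding protein Crabp1 (8.55-fold lower), Isg15 (7.97-fold), the cytokine Tslp (7.81-fold), Apol9a (7.34-fold), Apol9b (7.26-fold), Oasl2 (6.90-fold), Cd34 (5.89-fold) and the IL-33 receptor Il1rl1 (5.39-fold). Apol9a and Apol9b are near-identical paralogs whose reads may be split between them, so their separate values are uncertain. Highest by ratio was H19 (ENSMUSG00000000031, chromosome 7, 142575529 to 142578143), a long noncoding RNA expressed from the maternal allele, at 22.9 and 154 CPM, 6.74-fold higher in the UBD library (6.48 to 7.002). The epithelial keratin Krt18 was 11.7 and 76.4 CPM, 6.53-fold higher (6.19 to 6.89). H19 led cluster 1, which held 1.85% of control and 36.4% of UBD Y-negative cells, and Krt18 led cluster 2, with 5.84% and 30.8%. Serpinb2, Il11 and Crabp1 were among the leading genes of cluster 3, with 41.7% and 4.45%. These ratios pool over clusters of unlike shares, and no values within clusters are given for single genes. Cst6 was 3.32-fold higher, the basement membrane collagen Col18a1 3.30-fold, Ociad2 2.97-fold, Morc4 2.53-fold, the laminin receptor subunit Itga6 2.48-fold, and Galnt1 2.40-fold. Sec11c was 2.38-fold higher, Cenpv 2.32-fold, and both the desaturase Scd2 and the matrix gene Fbln2 2.21-fold.

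The fixed lists describe the same Y-negative cells. All 16 measured genes of the type I interferon response were at least 1.5-fold lower in the UBD library, with a median log2 ratio of -3.25 (-3.82 to -2.57), percentile 0 of 10000 random lists. Of the MHC class I presentation genes, 11 of 15 were at least 1.5-fold lower, with a median of -0.86 (-1.56 to -0.45). B2m, the light chain of MHC class I, was 1850 CPM in the control and 986 CPM in the UBD library, and the heavy chains H2-K1 and H2-D1 were 171 and 50.2 CPM and 698 and 309 CPM. Cd274, which encodes PD-L1, was 7.14 CPM (6.68 to 7.62) in the control and 3.08 CPM (2.81 to 3.36) in the UBD library. These low levels are within reach of free RNA, with Cd274 at 329 CPM in control neutrophil-like and 247 CPM in control dendritic-like cells, and without cluster 5 the log2 ratio was -0.29 in place of -1.21. NF-kB targets had a median of -0.97 (-1.77 to -0.65) with 12 of 15 at least 1.5-fold lower, among them Cxcl1 at 1017 and 271 CPM. Chemokines had a median of -1.45 (-2.96 to -0.39), with Ccl2, which attracts monocytes, at 1520 and 305 CPM. Levels in these cells were within reach of free RNA for 9 of the 16 type I interferon, 9 of the 15 MHC class I, 5 of the 15 NF-kB and 12 of the 16 chemokine genes. Cholesterol synthesis genes were higher, with a median of 0.50 (0.28 to 0.73), and Fdps, Cyp51 and Hmgcs1 were each 1.66-fold higher. Genes of dissociation stress had a median of -0.81 (-1.12 to -0.53), and Gm42418, a transcript that overlaps ribosomal RNA and is read as a sign of RNA quality, was 2851 CPM in the control and 1051 CPM in the UBD library. The FAT10 pathway list, at -0.04 (-0.38 to 1.70), and the proteasome core, at 0.02 (-0.21 to 0.13), lay near 0. Most Y-negative cells of the control library were in clusters 3 (41.7%), 5 (34.7%) and 10 (13.2%), and most of the UBD library in clusters 1 (36.4%), 2 (30.8%) and 6 (20.2%). Within each of the 6 clusters with at least 80 cells of both libraries the type I interferon list stayed below 0, from -2.20 to -0.63, while the MHC class I list was at 0.22 in cluster 5 and below 0 in the others. The NF-kB list ran from -0.44 to -0.18 within these clusters, chemokines from -1.14 to -0.41 and cholesterol synthesis from 0.18 to 0.67. Dissociation stress ran from -0.47 to 0.36 and was above 0 in 3 of the 6.

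Monocyte- or macrophage-like cells of the UBD library had lower levels of interferon-stimulated and monocyte-list genes and higher levels of MHC class II genes. Cell cycle genes were higher over the class as a whole but not within each of its clusters. Ly6c2 (ENSMUSG00000022584, chromosome 15, 75108158 to 75111970), a surface marker of inflammatory monocytes, was 1660 CPM in the control and 63.3 CPM in the UBD library, 26.2-fold lower there (24.4 to 28.2). Cluster 8, with Ly6c2 and Plac8 among its leading genes, held 23.6% of these cells in the control and 7.59% in the UBD library. Ifit1bl1 was 57.5-fold lower (32.7 to 112), Slfn4 41.7-fold (34.0 to 51.6), and the platelet chemokine Ppbp 32.2-fold (23.5 to 45.4). Further interferon-stimulated genes were Ifit3b (22.0-fold lower), Isg20 (17.9-fold), Ifit3 (17.5-fold), Mx1 (17.4-fold), Cmpk2 (15.1-fold), Usp18 (14.2-fold), Ifi208 (13.6-fold) and the interferon regulatory factor Irf7 (12.5-fold). Lyve1 (ENSMUSG00000030787, chromosome 7, 110850607 to 110863239), a hyaluronan receptor of resident macrophages, was 4.44 and 63.2 CPM, 14.2-fold higher in the UBD library (11.3 to 18.2). Cluster 21, with Lyve1 and Fcna among its leading genes, held 0.866% of these cells in the control and 4.98% in the UBD library. The leukotriene C4 synthase Ltc4s was 7.29-fold higher (5.99 to 8.94), Fxyd2 6.45-fold, the lectin Fcna 5.99-fold and the tetraspanin Cd81 4.61-fold. Pmepa1 was 4.57-fold higher, Cxcl9 4.46-fold (4.27 to 4.66), Pmp22 3.77-fold, Cd38 3.43-fold, Fcrls 3.27-fold, and Pdgfa and Anxa3 both 3.15-fold. Cxcl9 and Cxcl10, both induced by interferon gamma, went opposite ways, with Cxcl10 at 1262 CPM in the control and 452 CPM in the UBD library. As in the Y-negative cells, these ratios pool over clusters of unlike shares. No values within clusters are given for single genes, so a ratio may reflect which clusters the cells lie in.

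By list, all 16 type I interferon genes were at least 1.5-fold lower in the monocyte- or macrophage-like cells of the UBD library, with a median log2 ratio of -3.23 (-3.64 to -2.48). The monocyte list had a median of -1.70 (-3.32 to 0.40) with 7 of 9 genes at least 1.5-fold lower, and ran from -0.78 to -0.14 within clusters. Fn1 went the other way, 6.13-fold higher. MHC class II presentation had a median of 1.00 (-0.04 to 1.12), with 7 of 8 genes at least 1.5-fold higher, among them the invariant chain Cd74 at 3092 and 6056 CPM and H2-Ab1 at 1297 and 2663 CPM. MHC class I presentation, at -0.70 (-1.09 to -0.50), and the interferon gamma response, at -1.13 (-1.54 to -0.31), were lower. Cd274 was 180 CPM (174 to 187) in the control and 82.3 CPM (77.3 to 87.5) in the UBD library. G2/M genes had a median of 1.19 (1.00 to 1.46) with 16 of 18 at least 1.5-fold higher, among them Top2a at 39.7 and 112 CPM, and G1/S genes a median of 0.87 (0.39 to 1.02). Within clusters the G2/M list ran from -0.46 to 1.07 and the G1/S list from -0.75 to 0.31, each below 0 in 2 of 4. The interferon gamma list ran from -1.31 to 0.36 and was above 0 in clusters 0 and 4, while MHC class II was above 0 and type I interferon below 0 in all 4. The M2-type list had a median of 0.41 (-0.15 to 1.46), with Spp1 2.95-fold and Arg1 2.75-fold higher, and the M1-type list -0.58 (-1.48 to 2.16), with members on both sides. Cholesterol synthesis was at 1.04 (0.40 to 1.42) and glycolysis at 0.44 (0.09 to 0.65). Cluster 0 held 65.6% of these cells in the control and 4.94% in the UBD library, cluster 8 23.6% and 7.59%, and cluster 4 2.49% and 72.2%. Gm42418 was 11688 CPM in the control and 3041 CPM in the UBD library in these cells, and dissociation stress genes had a median of -0.76 (-1.004 to -0.53).

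**Figure D2:**
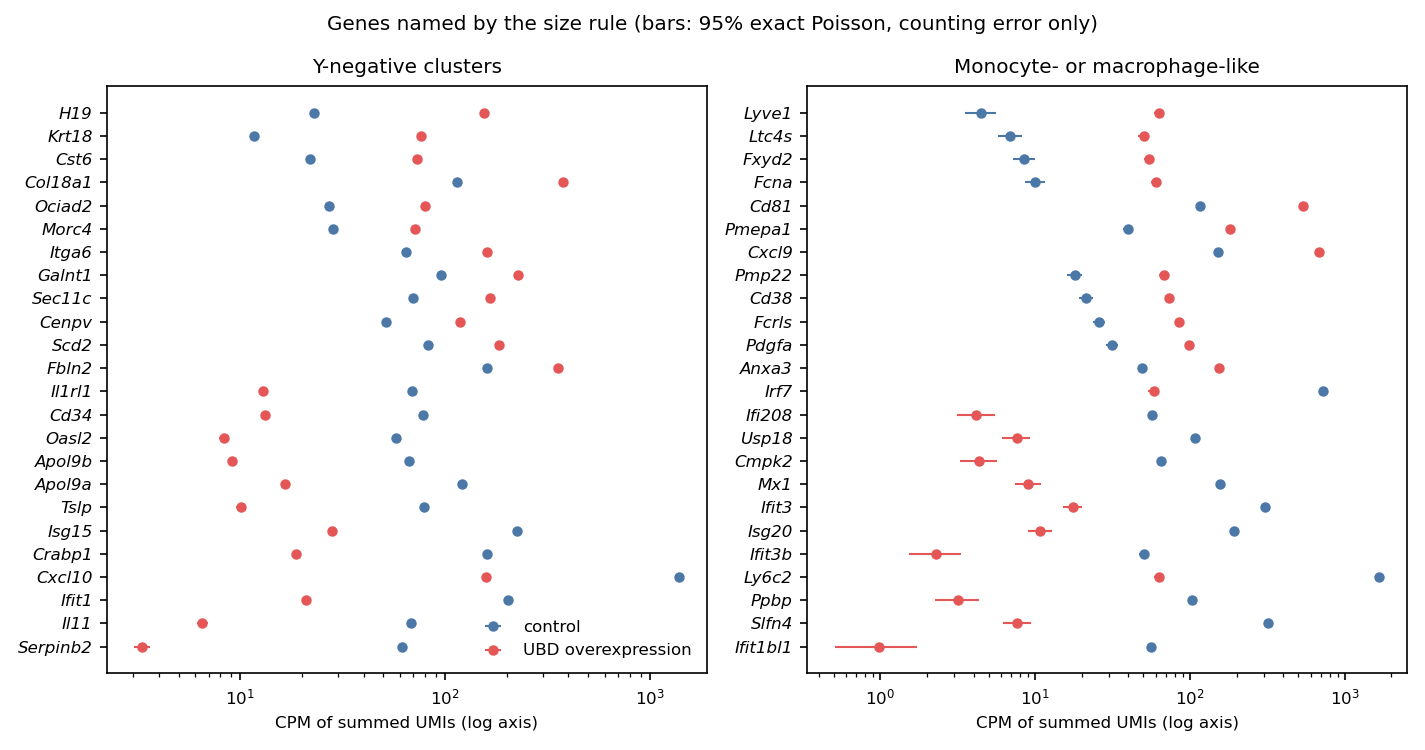
CPM of summed UMIs on a log axis for the genes named by size in the Y-negative clusters (left) and the monocyte- or macrophage-like cells (right), control and UBD libraries as points with exact Poisson intervals. H19 lies at 22.9 and 154 CPM at the top left, and Ly6c2 at 1660 and 63.3 CPM in the lower part of the right panel.

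T-like cells of the UBD library had more Ifng and less Gzmb, more often carried Cd8 transcripts when thinned to 1000 UMIs but not clearly so at 500, and had lower interferon-stimulated, regulatory and naive or memory T genes. Thinned to 1000 UMIs, 40.7% of 474 control cells (36.3 to 45.3) and 51.3% of 489 UBD cells (46.8 to 55.8) had a UMI of Cd8a or Cd8b1, a difference of 10.6 points (4.32 to 16.8). Cells with a Gzmb UMI, which encodes the cytotoxic protease granzyme B, were 63.7% and 49.7%, a difference of -14.0 points (-20.1 to -7.77). Cells with Foxp3, the regulatory T factor, were 4.43% and 2.04%, a difference of -2.39 points (-4.82 to -0.125). The intervals of the difference spanned 0 for Pdcd1 (10.5% and 11.9%), Havcr2 (7.38% and 7.98%), Tcf7 (4.64% and 3.07%), Mki67 (5.49% and 6.95%) and Cd4 (2.74% and 2.45%). Thinned to 500 UMIs, the difference was 5.07 points for Cd8a or Cd8b1 (-0.583 to 10.7) and -0.689 for Foxp3 (-2.61 to 1.13), both intervals spanning 0, and -12.4 for Gzmb (-18.3 to -6.30). Thinning to 1000 UMIs left out 26 control and 37 UBD cells. Without it the shares were 54.2% and 67.5% for Cd8a or Cd8b1, 71.6% and 64.1% for Gzmb, 9.20% and 3.80% for Foxp3, and 26.8% and 24.7% for Pdcd1. For Havcr2 they were 24.2% and 19.6%, for Tcf7 11.4% and 4.94%, for Mki67 13.4% and 12.4%, and for Cd4 6.60% and 4.75%. Median depths were 2883.5 and 2291.5 UMIs in T-like cells. In the thinned Y-negative cells, as background, shares were 0.142% and 0.0486% for Cd8a or Cd8b1, 0.508% and 0.109% for Gzmb, 0.0203% and 0% for Foxp3, and 0.0406% and 0% for both Pdcd1 and Cd4. They were 0.0813% and 0.0486% for Havcr2 and 0.488% and 0.644% for Tcf7. The Y-negative share for Mki67, 4.63% and 3.74%, reflects its own cycling cells and is no background.

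By level, Ifng (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892), the cytokine interferon gamma, was 304 CPM in the control and 661 CPM in the UBD T-like cells, 2.17-fold higher (1.96 to 2.41). Gzmb was 3453 and 1850 CPM, and Foxp3 38.7 and 18.0 CPM. Cd8a was 431 CPM (401 to 462) and 457 CPM (423 to 492). Pdcd1, the PD-1 gene, was 128 CPM (112 to 145) and 120 CPM (103 to 139). The chemokine Ccl1 was 8.09-fold higher in the UBD library (6.20 to 10.7), Tff1 5.13-fold (4.03 to 6.60), H1f0 3.39-fold, the cholesterol enzyme Hmgcs1 2.95-fold, Cd38 2.61-fold, Fdps 2.45-fold and Hist1h2bc 2.31-fold. Lower were Ifit3 (16.0-fold), Rtp4 (14.0-fold), Ifi213 (7.71-fold), Irf7 (6.95-fold), Mx1 (6.68-fold), Ifi27l2a (6.63-fold), Slfn1 (5.80-fold) and Xaf1 (5.53-fold), all interferon-stimulated. The type I interferon list had a median log2 ratio of -2.78 (-3.80 to -2.47) with all 16 genes at least 1.5-fold lower, 5 of them at levels that free RNA could reach. Regulatory T genes had a median of -0.78 (-1.14 to -0.12), with Tnfrsf4 at 488 and 309 CPM. Naive or memory T genes had a median of -1.01 (-1.73 to -0.03), with Ccr7 at 125 and 59.3 CPM. Of these 8 genes 5 were at least 1.5-fold lower and 3 were within reach of free RNA. Ccr7 also led dendritic-like cluster 20. The exhaustion list, at -0.09 (-0.60 to 0.30), and the cytotoxic effector list, at 0.01 (-0.90 to 0.56), lay near 0. Within the cytotoxic list Ccl5 was 1.48-fold and Ccl4 2.08-fold higher. Cholesterol synthesis had a median of 0.79 (0.35 to 1.29), glycolysis 0.40 (0.12 to 0.61) and G2/M 0.28 (0.16 to 0.38), the last at 0.0091 with doublets kept and 0.57 with cells weighted equally. Chemokines, at 0.24 (-1.49 to 1.06), and MHC class II, at -0.68 (-1.36 to 0.37), went the other way with at least 5 UMIs per gene (-0.054) and with doublets kept (0.94). Levels within reach of free RNA were those of 12 of 14 measured chemokine genes and all 6 measured MHC class II genes. Gm42418 was 13981 CPM in the control and 5694 CPM in the UBD T-like cells.

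The type I interferon list was lower in the UBD library in the remaining compared classes too. Its median was -2.87 (-3.72 to -2.27) in dendritic-like cells, -3.98 (-4.84 to -3.31) in the Acp5 and Ctsk cluster and -0.96 (-1.41 to -0.78) in fibroblast-like cells, where 13 of 16 genes were at least 1.5-fold lower. Cholesterol synthesis was above 0 in all 6 compared classes, except at -0.086 in fibroblast-like cells at Leiden resolution 0.5. Its medians ran from 0.44 in dendritic-like cells to 1.29 (1.05 to 1.82) in the Acp5 and Ctsk cluster, where Hmgcs1 was 3.52-fold (2.74 to 4.61), Scd2 3.22-fold and Idi1 2.69-fold higher. The lowest ratios in that cluster were Usp18 (31.6-fold lower), Irf7 (28.7-fold) and Ifit1 (24.2-fold). In dendritic-like cells Retnla was 24.7 and 1182 CPM, 47.9-fold higher (36.2 to 64.7), Lyz1 27.9-fold and Ear2 21.9-fold. Cluster 14, with Retnla among its leading genes, held 76.2% of these cells in the control and 69.6% in the UBD library. It had no dendritic marker among its leading genes and a marker score of 0.284, just above the limit. Cd74, H2-Ab1 and H2-Aa led both it and monocyte- or macrophage-like cluster 4, so these ratios may not be those of dendritic cells. Sct, a plasmacytoid dendritic cell transcript, gave 189 UMIs in the control and 1 in the UBD dendritic-like cells, a ratio of 0.0101 (0.000255 to 0.057). Cluster 22, led by plasmacytoid dendritic and B or plasma markers, stayed unnamed and was not compared. It held 50 control and 52 UBD cells, so the Sct ratio does not show fewer plasmacytoid cells in the UBD library. In the dendritic-like cells Chil3 gave 130 and 2 UMIs, a ratio of 0.0294 (0.00352 to 0.108), and Ifit3 was 30.3-fold lower. Chil3 turned to a log2 ratio of 1.08 at Leiden resolution 2.0. The G2/M list was at 1.46 (0.39 to 1.76) in dendritic-like cells, whose larger cluster was led by MHC class II genes. In fibroblast-like cells Nrcam was 7.05-fold higher (3.51 to 16.0), the Wnt ligand Wnt2 4.26-fold and Crip2 4.10-fold. Ankrd1, a target of YAP, was 24.97-fold lower (13.3 to 52.8), Tnfrsf9 16.2-fold and the EGF receptor ligand Ereg 9.01-fold. The fibroblast-like cells carried Cdkn2a at 610 CPM in the control and 224 CPM in the UBD library, against 1834 and 1780 CPM in the Y-negative cells. Whether this is RNA of Y-negative cells or their own was not tested. If it is RNA of Y-negative cells, the free RNA limit is too low for the fibroblast-like cells. The values of Ankrd1, a leading gene of Y-negative cluster 3, and of Tnfrsf9, at 23.4% of its highest level in another named class, may then include it.

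**Figure D3:**
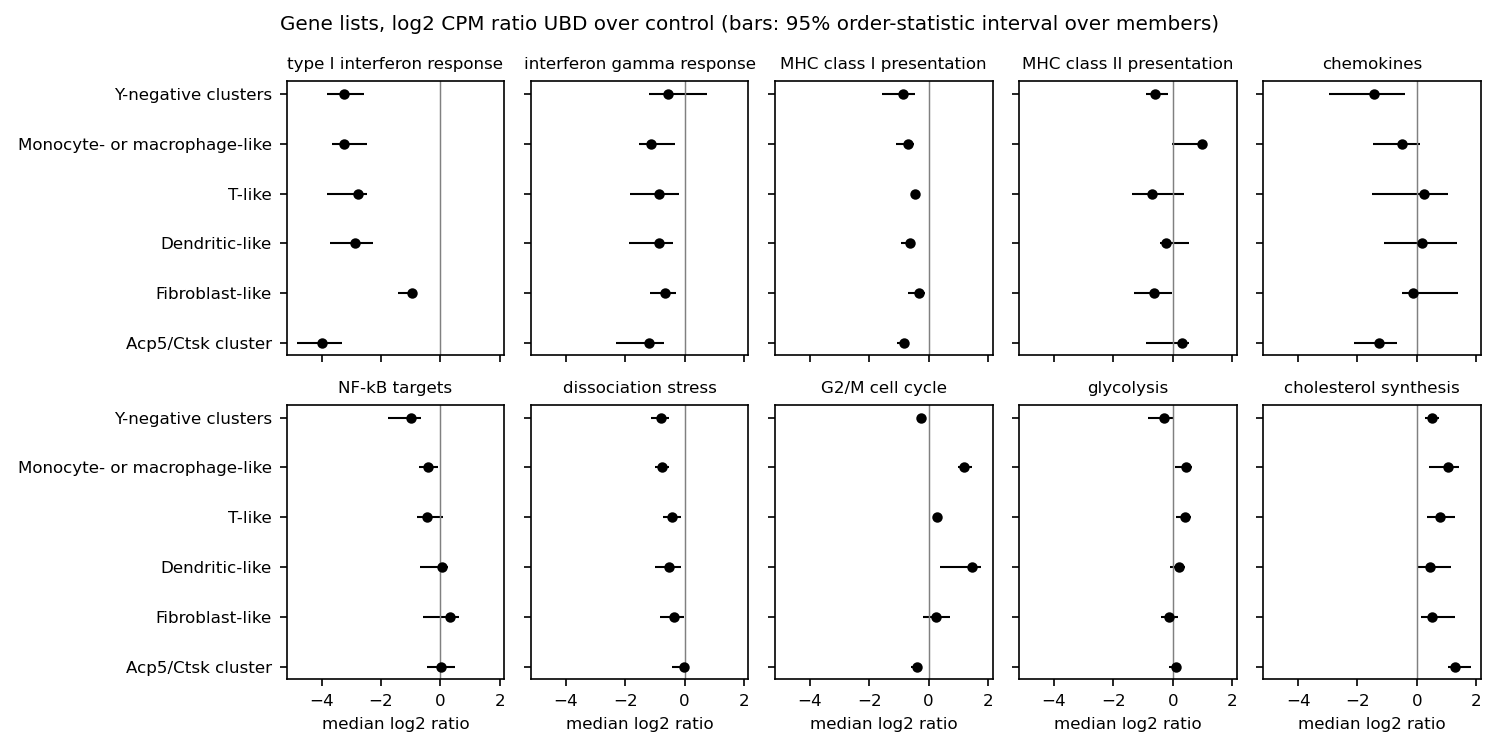
Median log2 ratio, UBD over control, of 10 of the fixed gene lists in the 6 compared classes, each point with its interval over the list's genes. The type I interferon medians run from -3.98 to -0.96 and the cholesterol synthesis medians from 0.44 to 1.29, each list on one side of 0 at the reported settings.

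The interferon gamma response was below 0 in all 6 classes, from -1.20 (-2.31 to -0.69) in the Acp5 and Ctsk cluster to -0.56 (-1.18 to 0.76) in the Y-negative cells, where it was above 0 in 4 of 6 clusters. MHC class I presentation was also below 0 in all 6, from -0.86 in the Y-negative to -0.34 in fibroblast-like cells. The cytotoxic effector list was at -2.34 in Y-negative, -1.998 in monocyte- or macrophage-like and -1.48 in dendritic-like cells, where 10 of 10, 9 of 10 and 7 of 9 genes were within reach of free RNA. Within the monocyte- or macrophage-like clusters it ran from -1.27 to 0.82 and was above 0 in 2 of 4. G1/S genes were at 1.04 in dendritic-like cells, turning to -0.20 at Leiden resolution 2.0, and at -0.56 in the Acp5 and Ctsk cluster, where chemokines were at -1.27 and G2/M at -0.39. Of the 16 chemokine genes in that cluster, 15 were at levels that free RNA could reach. Checkpoint ligands were at -0.64 (-3.45 to -0.37) in the Acp5 and Ctsk cluster, and in the other 5 classes their intervals spanned 0. Hypoxia genes were -0.35 (-1.03 to 0.11) in Y-negative cells, from -0.49 to 0.81 within clusters, and 0.45 (0.25 to 1.52) in the Acp5 and Ctsk cluster. Oxidative phosphorylation lay between 0.04 in T-like cells and 0.25 in the Acp5 and Ctsk cluster. The epithelial-mesenchymal list was at 0.00 (-0.68 to 0.62), TGF-beta targets at 0.07 (-0.74 to 0.79) and above 0 in all 6 clusters (0.07 to 0.74), Wnt targets at 0.02 (-1.79 to 0.43) and the unfolded protein response at -0.31 (-0.77 to 0.11) in Y-negative cells. Cytosolic ribosome genes were highest in monocyte- or macrophage-like cells, at 0.51 (0.16 to 0.64), and lowest in fibroblast-like cells, at -0.05. Mitochondrially encoded genes were at 0.38 (0.24 to 0.75) in monocyte- or macrophage-like cells and -0.13 (-0.34 to 0.29) in Y-negative cells. The sex-linked list in T-like cells was at -0.34 (-1.42 to -0.06), and the Y-linked sum in T-like cells was 178 and 141 CPM.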

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

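No test was chosen for this part, and the differences between classes below were not tested. They were picked out among the Y-negative, monocyte- or macrophage-like and T-like cells, where a fixed gene list had medians on opposite sides of 0, both with intervals excluding 0 and outside the middle 95% of random lists. MHC class II (-0.61 and 1.00) and G1/S (-0.15 and 0.87) were also on opposite sides in the Y-negative and the monocyte- or macrophage-like cells, but 1 interval of each pair spans 0. In the Y-negative cells all 8 MHC class II genes were within reach of free RNA. The G2/M list was at -0.25 in the Y-negative clusters and 1.19 in the monocyte- or macrophage-like cells, 1.44 apart on the log2 scale. T-like cells, at 0.28, lay 0.53 above the Y-negative clusters on the same list. The glycolysis list was at -0.29 in the Y-negative clusters and 0.44 in the monocyte- or macrophage-like cells, 0.73 apart, and at 0.40 in T-like cells, 0.69 apart. Within clusters these differences hold only in part. The G2/M list ran from -0.78 to 0.11 in the Y-negative clusters and from -0.46 to 1.07 in the monocyte- or macrophage-like ones, at -0.46 in cluster 4, which held 72.2% of the UBD cells of that class. With doublets kept the T-like G2/M median was 0.0091. The glycolysis list was nearer 0 within the 6 Y-negative clusters, from -0.17 to 0.17, and from 0.23 to 0.60 within the 4 monocyte- or macrophage-like ones.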

How the results depend on the processing

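Settings chosen after seeing the data were the shares without the unnamed clusters or with the largest of them counted as Y-negative, the values without cluster 5 and the list medians within clusters; the other settings were planned. Of all comparisons of a result with a setting, 1982 kept the value within its interval and direction, 210 moved past the interval in the same direction or without a called one, and 15 reversed. That interval covers counting error for shares and single genes, but for list medians it is the spread between the genes of a list. Many list intervals are wide, so a list median can shift much and still count as kept. The type I interferon list stayed below 0 in every compared class under each setting, from -4.16 to -0.96, and within the Y-negative and monocyte- or macrophage-like clusters from -2.33 to -0.63. The cause of the differences below was not tested unless stated. With at least 500 genes and at most 10% mitochondrial UMIs, the share difference in points was 32.4 for the Y-negative cells, 4.88 for the Acp5 and Ctsk cluster, -1.13 for endothelial-like, -18.1 for monocyte- or macrophage-like and -1.04 for neutrophil-like cells, and the M2-type list in the Acp5 and Ctsk cluster was -0.28. With doublets kept, share differences were 24.7 (Y-negative), -15.6 (monocyte- or macrophage-like), -2.77 (NK-like) and -0.159 (fibroblast-like). The same setting gave T-like list medians of 0.94 (MHC class II), 0.0091 (G2/M), -0.53 (MHC class I) and -0.80 (dissociation stress), TGF-beta targets at 0.021 in the Acp5 and Ctsk cluster and the cytotoxic list at -0.78 in fibroblast-like cells. At Leiden resolution 0.5 the share differences were 5.42 (Acp5 and Ctsk cluster) and -0.281 (fibroblast-like), and medians were -0.49 for the M2-type list in the Acp5 and Ctsk cluster and, in fibroblast-like cells, -0.086 for cholesterol synthesis and -1.43 for the cytotoxic list. At resolution 2.0 the dendritic-like share difference was -0.192, its G1/S median -0.20 and its Chil3 log2 ratio 1.08. With cells weighted equally, log2 values were 1.00 (Ubd, Y-negative), 0.57 (G2/M, T-like), -1.06 (MHC class II, Y-negative), -1.26 (dissociation stress, Y-negative) and 0.034 (epithelial-mesenchymal list, Acp5 and Ctsk cluster). With a minimum of 100 UMIs per gene, which leaves fewer genes per list, medians were 0.96 (exhaustion, Acp5 and Ctsk cluster) and 0.12 (hypoxia, fibroblast-like), and with a minimum of 5 the T-like chemokine median was -0.054. Without thinning, T-like share differences were -5.40 (Foxp3), -7.53 (Gzmb), -4.62 (Havcr2) and -6.46 (Tcf7). As shares of immune cells, differences were -4.40 (NK-like), 4.60 (T-like), 20.1 (Acp5 and Ctsk cluster), -18.4 (monocyte- or macrophage-like) and -2.59 (neutrophil-like), the denominator being smaller. Without cluster 5, 30 of 33 Y-negative log2 ratios of single genes and 3 of 30 list medians moved past their interval and 0 reversed; values were 2.82 (Ubd), -0.64 (NF-kB targets), -0.30 (dissociation stress) and, within its wide interval, -0.077 (interferon gamma, from -0.56). Without the unnamed clusters, share differences were -2.90 (NK-like), 23.8 (Y-negative), -1.78 (dendritic-like), -2.27 (endothelial-like), -21.8 (monocyte- or macrophage-like) and -1.59 (neutrophil-like). With the largest unnamed cluster counted as Y-negative, the Y-negative difference was 15.4. Without the free RNA filter, 12 of the 24 genes named in Y-negative cells, 21 of 24 in monocyte- or macrophage-like and 10 of 16 in T-like cells were still named. Some settings gave no value, among them the endothelial-like share at resolution 0.5 and the dendritic-like G2/M list at 2.0. Depth limits Ubd, with 111 and 204 UMIs over all cells. No paired analysis was possible because each group holds 1 library and no result comes from a test.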

Other observations

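Chosen after the result was seen were the tests of free RNA, of doublets and of leaving out the high-mitochondrial cluster. The genes of the first paragraph were also chosen after their values were seen.

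Ifnb1, which encodes interferon beta, gave 284 UMIs in the control and 19 in the UBD Y-negative cells, 2.23 against 0.119 CPM, a ratio of 0.0534 (0.0317 to 0.0850). In the monocyte- or macrophage-like cells it was similar in both libraries, with 55 and 44 UMIs and a ratio of 1.15 (0.753 to 1.74). The receptor genes Ifnar1 and Ifnar2 were 1.07-fold and 1.09-fold higher in the UBD library in the Y-negative cells and had ratios of 0.748 and 0.722 in the monocyte- or macrophage-like cells. Tnfsf11, which encodes the osteoclast-inducing cytokine RANKL, was 4.46 and 7.33 CPM in the Y-negative cells, 1.64-fold higher in the UBD library (1.48 to 1.82). Csf1, the macrophage growth factor, was lower there, at 64.4 and 35.3 CPM. In the NK-like cells, with 95 UBD cells, the type I interferon list had a median log2 ratio of -2.19 (-2.63 to -1.05), with all 16 genes lower in the UBD library. Ifng in these cells was 119 and 260 CPM and Gzmb 2665 and 1080 CPM, the same directions as in T-like cells.

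The type I interferon list was lower in the UBD library in every compared class. Free RNA from another named class is argued against as the whole cause in T-like cells only. There the median gene of the list stood in control cells at 5.24 times the largest free RNA share. In control NK-like cells it stood at 3.93 times. That was 13.4% of the highest class's level, within reach of free RNA as defined above. Other classes were not tested in this way. The highest level was taken over the named classes only. Unnamed cluster 7, with 1705 control cells and Ifit1, Cxcl10 and Rsad2 among its leading genes, was left out. As a source of free RNA it was not tested, and the multiples above may be too high. Of the 16 genes, 9 in Y-negative, 6 in fibroblast-like and 5 in T-like cells were within reach of free RNA. The fibroblast-like count may be too low, since these cells carried Cdkn2a at 610 CPM in the control library, against 1834 CPM in the Y-negative cells. In the Acp5 and Ctsk cluster 4 were, in dendritic-like cells 1 and in monocyte- or macrophage-like cells 0. With cells matched on Gm42418 the highest median of the 3 classes tested was -2.14 (T-like, -2.74 to -1.55), and with cells matched on depth it was -2.93, so neither RNA quality as read from Gm42418 nor depth could account for the whole pattern. A difference between the tumours or preparations other than UBD, with 1 library per group, cannot be told apart from an effect of UBD. An effect of UBD on interferon signalling remains an untested hypothesis.

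The Acp5 and Ctsk cluster held a larger share of the UBD library. Doublets of Y-negative cells and macrophages are argued against, since Cdkn2a in its UBD cells was 4.15% of its level in the Y-negative cells. With no clusters at all, 1.22% of control and 5.79% of UBD cells thinned to 1000 UMIs had UMIs of both genes, a ratio of 4.74 (3.99 to 5.66), above the ratio of 2 or less needed for clustering alone, though below the 7.89 of the cluster and with a lower bound just under the limit of 4 set beforehand. Taking off the share with both genes in Y-negative cells (0% and 0.328%) or in T-like cells (0% and 1.02%), as free RNA, left ratios of 4.47 and 3.91. A difference in which tissue was sampled may also give more such cells, and the design does not separate it from UBD.

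The Y-negative cells of the libraries lay in different clusters and differed in expression. Different copy number of whole chromosomes may contribute: 3 of 19 autosomes lay over 0.2 from all genes and 2 of them, 4 and 8, also over 0.2 from the monocyte- or macrophage-like value. The departure of a chromosome's median log2 ratio from that of all genes was largest on chromosome 4, at -0.28, with -0.25 on 8 and -0.27 on 14. These chromosomes were at 0.04, 0.04 and -0.09 in monocyte- or macrophage-like cells. Within the 6 Y-negative clusters chromosome 4 ran from -0.39 to -0.07 and chromosome 14 from -0.26 to -0.07. Chromosomes 1 and 2 were at 0.28 and 0.25 in cluster 2 and at 0.20 and 0.17 in cluster 6. In clusters 1, 3, 5 and 10 they lay between -0.03 and 0.10. The shifts on chromosomes 4, 8 and 14 are small beside the folds of the named genes, of which Isg15 lies on chromosome 4 and none on 8 or 14. DNA was not measured. The high-mitochondrial cluster 5 is argued against as the whole cause of the differences in expression, since without it the median gene past the naming rule kept 0.896 of its log2 ratio (0.872 to 0.913), though genes lower in the UBD library kept less, 0.821.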
